A study of Rattus norvegicus with 12 samples.

How the data were processed

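Total RNA from the renal cortex of 12 male rats (5 weeks old at purchase) was labelled with Cy3 from 0.2 ug and hybridised to one-colour Agilent rat arrays, 1 array per rat, per the labels' protocols. Rats were grouped from the labels by treatment (water, or TBA at 1000 mg/kg/day for 4 weeks) and by the gas used at the kill (CO2-O2 at 4:1, or isoflurane), with 3 in each group. The deposited scanner files hold spot intensity values from Agilent Feature Extraction 10.7 (10.7.1.1 per the file headers); the processed intensity is background-subtracted and detrended within an array and not normalized between arrays, per the file headers. The files hold no mean signal and no gene name column. The arrays lay on 3 slides scanned on 2 days: slide 1 held the vehicle CO2-O2 rats and TBA CO2-O2 rat 3, slide 2 held TBA CO2-O2 rats 1 and 2 and the vehicle isoflurane rats, and slide 3 held the TBA isoflurane rats. Slide 1 was scanned on day 1 and the others on day 2.

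The submitters' series table was set against the scanner files. Its values are a ratio of the processed intensity to the array's 75th percentile on a linear scale, with column medians of 0.101 to 0.107, a scale found from the values and not stated by the authors. Each of its 12 columns matched (r = 0.9999) the scanner file of another replicate of the same group, so replicate numbers here are those of the scanner files and group membership is the same in both. No centring of genes was found, and a one-colour signal has no direction.

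Probe accessions were matched without versions to the RefSeq table of the GRCr8 assembly, which was used for names only: 27460 of 61657 probes had 1 symbol, 0 had several and 34197 had none, for 15284 symbols. Log2 of the processed signal minus each array's 75th percentile was the value analysed. Control and outlier-flagged spots were left out. The 40216 probes well above background on all 3 arrays of at least 1 group were kept, and for each symbol the kept probe with the highest mean signal was used, which left 29603 features. The number of arrays limits the precision.

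One mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 1.89 prior degrees of freedom) with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Contrasts were the TBA effect under each anesthetic, their mean, their difference, and isoflurane minus CO2-O2 in vehicle and in TBA rats. Lists of functions and cell types fixed before the data were examined (48 with at least 3 tested genes) were tested with camera at a preset correlation of 0.01, adjusted over the lists within each comparison. Genes were named by a rule fixed at the same time: the 8 with the highest rise and the 8 with the largest fall among those called whose groups did not overlap, up to 4 members of a list with a call, and a preset group always. That group was Havcr1, Lcn2, Clu, Spp1, Mki67, Top2a, Cyp2b1, Cyp1a1 and Lrp2 for TBA, and Fos, Egr1, Atf3, Per1, Vegfa and Pck1 for the anesthetics. The rule let fewer be named where space was short, and Mki67, Top2a, Cyp2b1 and Cyp1a1 are not given here. Other genes that illustrate a figure or a list were chosen after their values were seen. For a gene not well above background on any array of a group, a bound is given: the bright group's mean against the dim group's, each dim array taken at the higher of its lowest well-measured signal and the probe's own.

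The fit was tested on simulated arrays with the means and spreads of 29582 features, 200 of them changed, in 10 draws. For the TBA effect under CO2-O2 it recovered 38.1%, 73.1% and 91.7% of log2 changes of 0.5, 1 and 2, with 9.7 false calls among 144.7 on average; for the averaged effect it recovered 57.0%, 83.6% and 96.4%. A list of 20 genes raised by 0.3 was called by camera in 10 of 10 draws, and in 10 of 10 with an estimated correlation. The simulated features varied independently and had no slide effect. These draws therefore do not show how either list test behaves with correlated genes.

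Alternatives fixed before the data were examined were normexp background correction (offset 50, on the median signal because the files lack the mean), quantile and median scaling, the submitters' table, no filter or a stricter filter on dim probes, the mean of a gene's probes, slide as a random block (duplicateCorrelation with statmod 1.5.0, consensus correlation 0.0671) or a fixed term, replicate number as a block, only the arrays compared, a trend with robust spread, array weights, a fold of at least 2, an estimated correlation or fry for lists, and each array left out in turn. Scan day as a fixed term, slide 1 or scan day 2 alone, and only features with a symbol were added after seeing the data. No genome coordinates are given, since the array annotation and the name table use different builds.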

Results

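Expression was measured with one-colour microarrays in the renal cortex of 12 male Sprague-Dawley rats, 1 array per rat. Rats received water (vehicle) or tert-butyl alcohol (TBA, a solvent and a metabolite of the fuel additives MTBE and ETBE) at 1000 mg/kg/day for 4 weeks and were bled 24 h after the last dose. Some were killed under a CO2-O2 mixture and others under isoflurane, which gives 4 groups of 3 rats, described in the labels as biological replicates. Between 61.6% and 71.0% of the 61657 non-control probes were well above background on each array, and arrays of a group correlated at 0.989 to 0.994. After filtering, 29603 features were tested, 11689 of them genes with a symbol and 17914 accessions without one. Differences are log2 fold changes with the standard error (SE) from limma and n = 3 rats per group. For each gene named by size every array of one group lay on the same side of every array of the other.

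The first comparison asked what TBA did to the renal cortex in rats killed under CO2-O2. The highest rises among named genes were in Cldn24 and Cldn22, neighbouring genes for tight junction claudins, with log2 changes of 2.66 ± 0.27 (adjusted p = 0.0116) and 2.25 ± 0.23 (adjusted p = 0.0116). Hrh4, a histamine receptor, rose by 1.53 ± 0.18 (probes from 0.50 to 1.53) and Nus1, a subunit of the enzyme that makes dolichol precursors, by 1.44 ± 0.15. The transcription factors Tcf15 and Pax3 rose by 1.07 ± 0.11 and 0.94 ± 0.12. Acot12, a cytosolic acetyl-CoA hydrolase, rose by 0.93 ± 0.07 (adjusted p = 0.00311). Igf1, a growth factor, fell by 0.91 (SE 0.13, adjusted p = 0.0318), and Gckr, the glucokinase regulator, fell by 0.48 (SE 0.07, adjusted p = 0.0401). The rise in Nus1 was seen with 2 of its 3 probes and that in Tcf15 with 1 of its 2.

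Markers of the S1-S2 segments of the proximal tubule were higher as a list in the TBA rats under CO2-O2, and those of the S3 segment were not called (mean -0.18 ± 0.19, SE between rats, over 10 members). Of 12 markers of the S1-S2 segments, 10 were higher (median 0.24). Of these 1 rose, the sodium-lactate cotransporter Slc5a12 (0.80 ± 0.12, adjusted p = 0.0421), and 5 rose when adjusted over the list alone. The list's camera adjusted p was 0.000891, and its adjusted p = 0.579 with an estimated correlation. Within slide 1, which held 1 TBA array and 3 vehicle arrays under CO2-O2, the mean of the S1-S2 markers was 0.35 ± 0.07 (SE over 12 members, which gives no spread between rats). In the same comparison the mean of the markers was 0.23 ± 0.05 (here SE between rats) for the distal convoluted tubule, 0.16 ± 0.05 for intercalated cells, 0.14 ± 0.05 for endothelium and 0.14 ± 0.08 for podocytes. It was -0.26 ± 0.08 for fibroblasts, -0.20 ± 0.08 for the thick ascending limb and -0.13 ± 0.12 for collecting duct principal cells. Of these 7 lists camera called the thick ascending limb alone. Among genes of gluconeogenesis and ammoniagenesis, 1 of 21 rose, Pck1, the enzyme that makes phosphoenolpyruvate (0.53 ± 0.08, adjusted p = 0.0474). Adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.0128; adjusted p = 0.579 with an estimated correlation, and 0.0201 with fry). PPAR-alpha targets, genes of fatty acid oxidation, had 25 of 30 members higher and a median of 0.19. None was called over all genes and 1 was when adjusted over the list alone (camera adjusted p = 0.00453; adjusted p = 0.623 with an estimated correlation).

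The alpha-2u-globulin family holds urinary proteins of male rats, near-identical paralogs whose single members are uncertain. It had a median log2 change of -2.70 over 4 members under CO2-O2 (camera adjusted p = 0.00586; adjusted p = 0.623 with an estimated correlation). No member passed over all genes and 3 fell when adjusted over the list alone. The signal of Mup5 was -3.96 and -4.46 in TBA rats 1 and 2 but -1.21 in TBA rat 3, against -0.67, -0.36 and -0.25 in the vehicle rats. TBA rat 3 was the TBA array on the vehicle rats' slide, and with slide as a fixed term the alpha-2u-globulin median was -0.73 (adjusted p = 0.515). Within slide 1 it was also -0.73, from that 1 TBA array, so differences between rats cannot be separated from a TBA effect there. Genes of the thick ascending limb (median -0.21 over 9 members; camera adjusted p = 0.0401, adjusted p = 0.729 with an estimated correlation) were lower, with no member called over all genes. So were those of the renin-angiotensin system (-0.43 over 10; 0.0486, and adjusted p = 0.579 with an estimated correlation) and of cholesterol synthesis (-0.11 over 21; 0.0299, and adjusted p = 0.740 with an estimated correlation). Skeletal muscle markers had a median of 0.30 over 6 members (camera adjusted p = 0.0498; adjusted p = 0.579 with an estimated correlation). Without TBA array 1 of this arm the skeletal muscle median was 0.05 (adjusted p = 0.191) and that of cholesterol synthesis -0.06 (adjusted p = 0.110), and without vehicle array 2 the latter was -0.06 (adjusted p = 0.102). The renin-angiotensin median was -0.13 without the filter on dim probes (adjusted p = 0.0497), -0.35 without TBA array 3 (adjusted p = 0.159) and -0.31 without TBA array 2 (adjusted p = 0.0936). The injury markers Lcn2 (1.05 ± 1.03, adjusted p = 0.688), Spp1 (0.94 ± 0.42, adjusted p = 0.354), Clu (0.77 ± 0.26, adjusted p = 0.234) and Havcr1 (0.24 ± 0.52, adjusted p = 0.871) did not pass.

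By limma with an adjusted p under 0.05, 44 features differed under CO2-O2, 38 higher and 6 lower. Of these 26 had a symbol and 9 changed at least 2-fold. At an unadjusted p under 0.05 there were 4219, where chance gives 1480. Of all features 20.9% had groups that did not overlap, where chance gives 10%. The count was 1, 2 and 1 without vehicle array 1, 2 or 3 of this arm, 1, 3 and 162 without TBA array 1, 2 or 3, and 27 and 26 without TBA isoflurane array 2 or 3. Without TBA array 3, the 1 TBA array on the slide of the vehicle rats, TBA and slide cannot be told apart in this arm. With slide as a fixed term, and within slide 1, the effect rests on that 1 TBA array, so no count is given here.

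**Figure D1:**
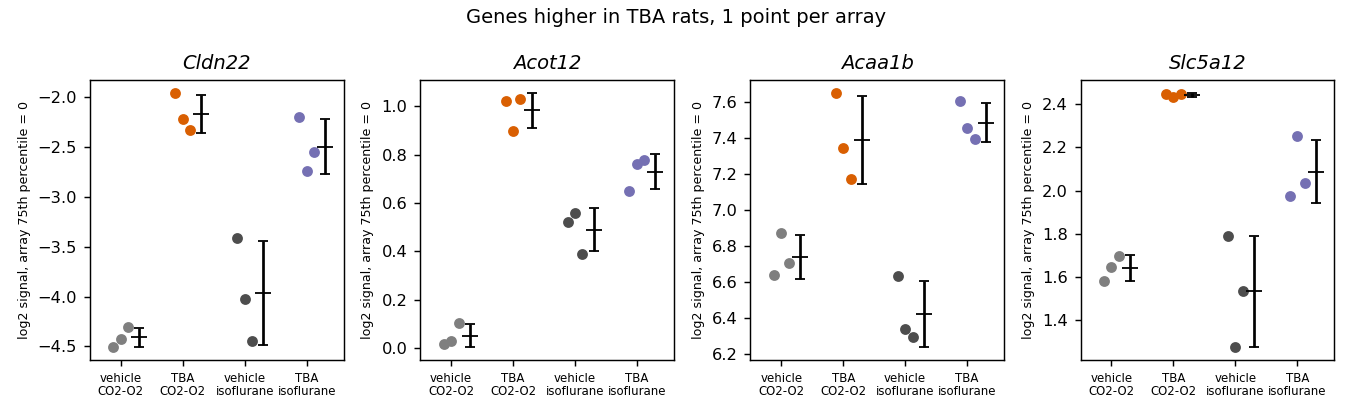
Signal of Cldn22, Acot12, Acaa1b and Slc5a12 on each array (points, log2 relative to the array's 75th percentile) in the 4 groups of 3 rats, with the group mean and SD beside the points. Cldn22 and Slc5a12 lie higher in TBA than in vehicle rats under both anesthetics.

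The same question was asked in rats killed under isoflurane. Bmal1, an activator of the circadian clock, rose by 1.92 ± 0.30 (adjusted p = 0.0377), and Cldn22 by 1.47 ± 0.23 (adjusted p = 0.0430). Wsb1, an adaptor of a ubiquitin ligase, rose by 1.11 ± 0.10 (adjusted p = 0.0214), and the peroxisomal thiolase Acaa1b by 1.06 ± 0.13 (adjusted p = 0.0316). Rises were also seen in the stress-responsive gene Ndrg1 (0.98 ± 0.16) and the mitochondrial enzyme Glud1, which releases ammonia from glutamate (0.71 ± 0.10). Among the genes that fell were Doc2a, a calcium sensor of vesicle release (-1.90 ± 0.26, adjusted p = 0.0363, well above background on 1 of 3 TBA arrays), and Sik1, a salt-inducible kinase (-0.76 ± 0.12, adjusted p = 0.0363). Rd3l and the neuromedin B receptor Nmbr were not well above background on any TBA isoflurane array and were at least 2.08-fold (adjusted p = 0.0487) and at least 2.61-fold (adjusted p = 0.0363) lower there. The olfactory receptor Or12j3 was lower (adjusted p = 0.0214), but it was well above background on 2 of 3 vehicle arrays and on no TBA array under isoflurane, so its size is not given, and with normexp it did not pass (adjusted p = 0.305). The rise in Notch3 (0.51 ± 0.08) was seen with 1 of its 2 probes, and the probes of Ptprn2 ranged from -0.75 to -0.06.

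PPAR-alpha targets were higher in 28 of 30 members under isoflurane, with a median of 0.40; 1 rose over all genes (Acaa1b) and 15 when adjusted over the list alone. The pantetheinase Vnn1 was at 1.08 ± 0.21 (adjusted p = 0.0667). The list's camera adjusted p was 1.05e-07, with adjusted p = 0.562 under an estimated correlation and 0.0359 with fry. Genes of oxidative phosphorylation were higher in 25 of 27 members, with a median of 0.15 that turned to -0.04 under quantile normalization (camera adjusted p = 0.000319; adjusted p = 0.822 with an estimated correlation). Heat shock genes were higher in 16 of 17 members (median 0.17, camera adjusted p = 0.00202; adjusted p = 0.822 with an estimated correlation). Markers of the proximal tubule S1-S2 segments (median 0.20) and of the S3 segment (0.27), glutathione and glucuronosyl transferases (0.33) were higher as lists. So were genes of alcohol and aldehyde oxidation (0.14), interferon response genes (0.36) and red blood cell markers (0.34). Their camera adjusted p lay between 0.0311 and 0.0407. Each lost that with an estimated correlation, with adjusted p = 0.968 for interferon genes and 0.822 for the others. Without TBA isoflurane array 2 the interferon median was 0.05 (adjusted p = 0.986). Without array 1 the medians were 0.12 for S3 markers (adjusted p = 0.222), 0.22 for red blood cell markers (adjusted p = 0.215), 0.08 for alcohol and aldehyde oxidation (adjusted p = 0.133) and 0.06 for oxidative phosphorylation (adjusted p = 0.0465). Without vehicle isoflurane array 1 the S3 median was 0.14 (adjusted p = 0.134). With quantile normalization the S1-S2 median was 0.01 (adjusted p = 0.917) and that of alcohol and aldehyde oxidation 0.05 (adjusted p = 0.638).

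The circadian clock list had a median of -0.43 under isoflurane, with 4 of 16 members higher and 12 lower (camera adjusted p = 0.0407; adjusted p = 0.562 with an estimated correlation). Over all genes 1 rose, Bmal1, and adjusted over the list alone 3 rose and 7 fell. The alpha-2u-globulin list had a median of -1.94 with no member called either way of adjusting (camera adjusted p = 0.0407; adjusted p = 0.822 with an estimated correlation). Lcn2 (-1.23 ± 1.03, adjusted p = 0.578), Spp1 (1.06 ± 0.42, adjusted p = 0.234) and Havcr1 (-0.12 ± 0.52, adjusted p = 0.934) did not pass.

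Under isoflurane 117 features differed by limma, 74 higher and 43 lower, of which 57 had a symbol and 22 changed at least 2-fold. In all 5282 had an unadjusted p under 0.05, where chance gives 1480, and the groups did not overlap for 24.0%, where chance gives 10%. The count was 0, 10 and 3 without vehicle CO2-O2 array 1, 2 or 3, 30 and 54 without TBA CO2-O2 array 1 or 2, 57, 0 and 2 without vehicle isoflurane array 1, 2 or 3, and 5, 0 and 1 without TBA isoflurane array 1, 2 or 3. The TBA isoflurane arrays filled a slide of their own, so slide could not be a fixed term here. With slide as a random block the count was 0, and from the arrays of scan day 2 alone 0. With scan day as a fixed term it was 98, the same as without TBA CO2-O2 array 3. All isoflurane arrays were scanned on day 2, so that term cannot correct this comparison for scan day.

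The TBA effect averaged over both anesthetics used all 12 rats. Cldn24 rose by 2.03 ± 0.19 (adjusted p = 0.00421), Cldn22 by 1.86 ± 0.17 (adjusted p = 0.00363), Bmal1 by 1.54 ± 0.21 (adjusted p = 0.0148) and Mttp, which loads lipid onto lipoproteins, by 1.40 ± 0.24 (adjusted p = 0.0292, well above background on 2 of 3 vehicle isoflurane arrays). Timm8a2, of a mitochondrial import family, fell by 1.58 (SE 0.26, adjusted p = 0.0287), Tmod1, which caps actin filaments, by 1.55 (SE 0.24, adjusted p = 0.0230), and the receptor phosphatase Ptprq by 1.54 (SE 0.31, adjusted p = 0.0433). Fancd2, a DNA repair gene, fell by 0.83 (SE 0.13, adjusted p = 0.0259, well above background on 2 of 3 TBA isoflurane arrays). The probes of Htr3a ranged from 0.37 to 1.21 and those of Tmod1 from -1.55 to -0.83, and the fall of Pou2af1 (-0.73 ± 0.14) came from 1 of its 2 probes.

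Of 30 PPAR-alpha targets, 27 were higher in the averaged effect (median 0.29), 5 rose over all genes and 14 when adjusted over the list alone. They include Vnn1 (0.88 ± 0.15, adjusted p = 0.0292), Acaa1b (0.86 ± 0.10, adjusted p = 0.00579) and the lipid droplet protein Plin2 (0.47 ± 0.08, adjusted p = 0.0292). The list's camera adjusted p was 9.34e-08, with adjusted p = 0.535 under an estimated correlation and 0.0104 with fry. Its mean was 0.43, against 0.56 ± 0.15 within scan day 2 and 0.30 ± 0.14 within slide 1. These SEs are over the 30 members, and slide 1 holds 1 TBA array. Between rats the SE within scan day 2 was 0.22, and without vehicle isoflurane array 3 that mean was 0.35. Of 12 proximal tubule S1-S2 markers, 10 were higher (median 0.19). Of these 2 rose, Slc5a12 (0.68 ± 0.08, adjusted p = 0.00986) and the organic anion transporter Slc22a8 (0.38 ± 0.06, adjusted p = 0.0292). When adjusted over the list alone 7 rose, while the endocytic receptor Lrp2 stood at 0.05 ± 0.06 (adjusted p = 0.669). The S1-S2 list's camera adjusted p was 0.000243, with adjusted p = 0.673 under an estimated correlation and 0.0148 with fry. With quantile normalization its median was 0.06 (adjusted p = 0.106).

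Of 21 genes of gluconeogenesis and ammoniagenesis, 3 rose, among them Glud1 (0.63 ± 0.07, adjusted p = 0.00751) and Pck1 (0.36 ± 0.06, adjusted p = 0.0257). In all 5 rose adjusted over the list alone. As a list they did not pass camera (adjusted p = 0.0655) and passed fry (adjusted p = 0.0104). Oxidative phosphorylation genes had a median of 0.10 with 1 of 27 called, Cox4i1 (0.19 ± 0.04, adjusted p = 0.0418), and 6 adjusted over the list alone (camera adjusted p = 0.000242; adjusted p = 0.835 with an estimated correlation), but -0.01 under quantile normalization. Heat shock genes had a median of 0.13 (camera adjusted p = 0.00474; adjusted p = 0.731 with an estimated correlation). The 4 alpha-2u-globulin members had a median of -2.32, with none called over all genes and 4 lower when adjusted over the list alone. The list's camera adjusted p was 0.00175, with adjusted p = 0.731 under an estimated correlation. With scan day as a fixed term the median was -1.34, and its CO2-O2 part then rests on 1 TBA array. Clock genes went both ways. Bmal1 and its partner Npas2 (0.88 ± 0.14, adjusted p = 0.0270, probes from 0.18 to 0.88) rose and the output factor Tef fell by 0.50 (SE 0.10, adjusted p = 0.0427). The list as a whole did not pass (median -0.31, camera adjusted p = 0.0580). The immediate early gene Fos rose by 0.80 ± 0.14 (adjusted p = 0.0291), and the claudin Cldn10, placed in the thick ascending limb list, fell by 0.40 (SE 0.08, adjusted p = 0.0417).

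The averaged effect held 558 features past the threshold in limma, 413 higher and 145 lower, 217 of them with a symbol, and 31 changed at least 2-fold. In all 5639 had an unadjusted p under 0.05. With slide as a random block the count was 324. With scan day as a fixed term the CO2-O2 part of the effect rests on 1 TBA array, so no count is given here. The count was 73, 158 and 113 without vehicle CO2-O2 array 1, 2 or 3, and 95, 135 and 992 without TBA CO2-O2 array 1, 2 or 3. It was 257, 112 and 86 without vehicle isoflurane array 1, 2 or 3, and 259 and 84 without TBA isoflurane array 1 or 2. Without TBA CO2-O2 array 3, TBA and slide cannot be told apart under CO2-O2.

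Across the 29603 features, the TBA effects under the 2 anesthetics, which share no arrays, correlated at r = 0.187 (rho = 0.154; genes are not independent replicates), and 55.4% had the same direction. The correlation was 0.250 without TBA isoflurane array 1 and 0.0639 without array 2. Of the 44 features called under CO2-O2, 42 had the same direction under isoflurane, and of the 117 called under isoflurane, 84 had the same direction under CO2-O2. The 2 tests share 1 estimate of the spread, so their calls are not independent. Features called in both numbered 8, of which 7 had the same direction, where independent lists would share 0.0950 higher and 0.00872 lower. The other, an accession without a symbol, was at -0.37 under CO2-O2 and 0.36 under isoflurane. Cldn22, Wsb1, Hivep3 and Spag7 rose in both and Spata6 fell in both. The test of the difference between the effects called 0 features with limma, with 3578 at an unadjusted p under 0.05 where chance gives 1480. The smallest adjusted p was 0.0728, for the lipase gene Abhd16a. That count was 5 and 2 without vehicle isoflurane array 1 or 3. With scan day as a fixed term the CO2-O2 effect rests on 1 TBA array, so no count is given here.

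**Figure D2:**
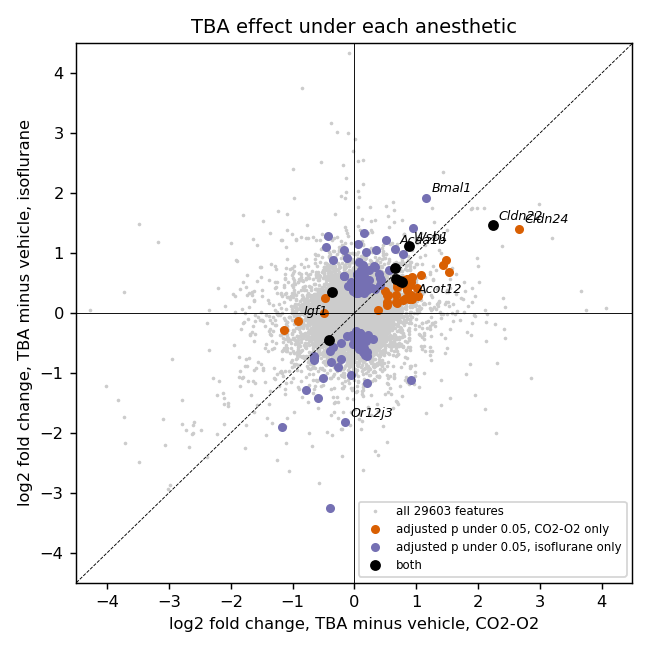
Log2 fold change of TBA against vehicle under CO2-O2 (x axis) and under isoflurane (y axis) for the 29603 features, with those past an adjusted p of 0.05 in colour and the dashed line at equal effects; 4 features lie outside the axes. Cldn22 and Wsb1 lie high on both axes, and most called features have the same sign on both.

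The next comparison asked how expression differed between the anesthetics in rats given water. The vehicle CO2-O2 arrays lay on slide 1, scanned on day 1, and the vehicle isoflurane arrays on slide 2, scanned on day 2. Within these rats the anesthetic cannot be told apart from slide and scan day. The vehicle isoflurane arrays also enter the TBA effect under isoflurane, with the opposite sign. Opposite changes in that effect and in this comparison are therefore not independent. Bmal1 fell by 2.44 (SE 0.30, adjusted p = 0.0304) under isoflurane relative to CO2-O2, and Per3, of the repressing arm of the clock, rose by 0.60 ± 0.08 (adjusted p = 0.0366), with its 5 probes between 0.60 and 1.26. Sik1, which responds to cAMP signalling, rose by 0.87 ± 0.12 (adjusted p = 0.0366), the kinase Stk35 by 0.72 ± 0.07 (adjusted p = 0.0173, probes from 0.30 to 0.72), and Abhd16a by 1.11 ± 0.16 (adjusted p = 0.0487). Tnfrsf11b, the decoy receptor osteoprotegerin, fell by 2.40 (SE 0.35, adjusted p = 0.0487), and the phosphate transporter Slc34a2 by 1.81 (SE 0.17, adjusted p = 0.0173). Falls were also seen in the Notch ligand Jag1 (-0.86 ± 0.11, adjusted p = 0.0348) and Wsb1 (-0.78 ± 0.10, adjusted p = 0.0348). The probes of Shbg (0.80 ± 0.10) ranged from 0.14 to 0.80.

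The clock list was higher in 12 of 16 members in vehicle rats under isoflurane, with a median of 0.59. Over all genes Per3 rose and Bmal1 fell, and adjusted over the list alone 9 rose and 2 fell. Its camera adjusted p was 0.0140, with adjusted p = 0.420 under an estimated correlation and 0.0102 with fry. Per2 (1.00 ± 0.15, adjusted p = 0.0557) and Ciart (2.45 ± 0.60, adjusted p = 0.101) did not pass over all genes. Red blood cell markers were lower as a list (median -0.50 over 9 members, camera adjusted p = 0.00412; adjusted p = 0.553 with an estimated correlation), as were cytokines and NF-kB targets (-0.53 over 23, 0.00412, and adjusted p = 0.553 with an estimated correlation). The same holds for markers of the S3 segment (-0.43 over 10, 0.00448, and adjusted p = 0.553 with an estimated correlation), PPAR-alpha targets (-0.21 over 30, 0.00523, and adjusted p = 0.553 with an estimated correlation) and B and plasma cell markers (-0.73 over 4, 0.0385, and adjusted p = 0.553 with an estimated correlation). Fibroblast markers (-0.40 over 6, 0.0288, and adjusted p = 0.420 with an estimated correlation) and extracellular matrix genes (-0.24 over 19, 0.0289, and adjusted p = 0.689 with an estimated correlation) were also lower. Markers of S1-S2 (0.14 over 12, 0.0339, and adjusted p = 0.596 with an estimated correlation) and of intercalated cells (0.18 over 10, 0.0385, and adjusted p = 0.689 with an estimated correlation) were higher. The extracellular matrix median was -0.03 with slide as a fixed term (adjusted p = 0.850) and -0.08 without vehicle isoflurane array 2 (adjusted p = 0.332). The S1-S2 median was 0.09 without vehicle isoflurane array 1 (adjusted p = 0.188). Mean signals in vehicle CO2-O2, TBA CO2-O2, vehicle isoflurane and TBA isoflurane rats were 2.67, 2.59, 2.19 and 2.55 for red blood cell markers. For S3 markers they were 2.11, 1.92, 1.52 and 1.94 in that order. In both lists the vehicle isoflurane group was lowest, and it is also the reference of the TBA effect under isoflurane. The mean of the PPAR-alpha list was -0.27 ± 0.24 (SE between rats) and -0.06 without vehicle isoflurane array 3, where its median was -0.18 (adjusted p = 0.087), and with normexp the median was -0.12 (adjusted p = 0.120). The immediate early genes Fos (0.25 ± 0.19, adjusted p = 0.509), Egr1 (-0.19 ± 0.24, adjusted p = 0.706) and Atf3 (-0.38 ± 0.35, adjusted p = 0.576) and the hypoxia target Vegfa (-0.02 ± 0.08, adjusted p = 0.909) did not differ past the threshold.

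In vehicle rats 31 features differed between the anesthetics by limma, 17 higher and 14 lower, 18 of them with a symbol, and 11 changed at least 2-fold. In all 5530 had an unadjusted p under 0.05, where chance gives 1480, and the groups did not overlap for 29.1%, where chance gives 10%. With median scaling 32.7% of 52 calls were higher, against 54.8% of the 31. With slide as a fixed term, which rests on TBA CO2-O2 arrays of slides 1 and 2, the count was 36, of which 2 were among the 31, and with slide as a random block 3. It was 1, 2 and 0 without vehicle CO2-O2 array 1, 2 or 3, 15, 0 and 10 without vehicle isoflurane array 1, 2 or 3, 19 and 91 without TBA CO2-O2 array 1 or 3, and 4 and 0 without TBA isoflurane array 2 or 3.

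**Figure D3:**
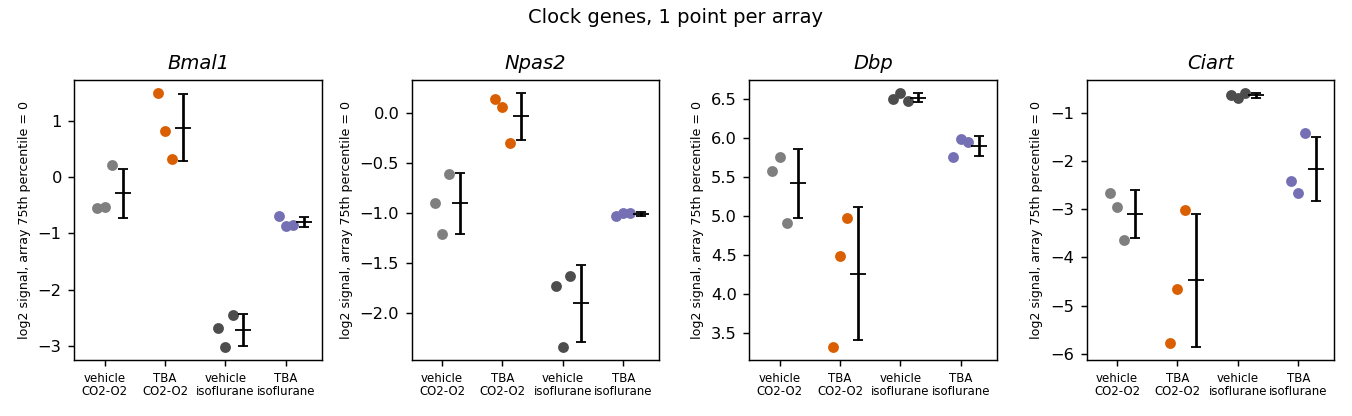
Signal of the clock genes Bmal1, Npas2, Dbp and Ciart on each array (points, log2 relative to the array's 75th percentile) in the 4 groups of 3 rats, with the group mean and SD beside the points. Bmal1 lies lower and Ciart higher in vehicle rats under isoflurane than in vehicle rats under CO2-O2.

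In TBA rats, the anesthetics differed for 2 features, Or12j3, an olfactory receptor that was lower under isoflurane (adjusted p = 0.0231; 0.181 with normexp) and well above background on 2 of 3 TBA arrays under CO2-O2 and none under isoflurane, and 1 accession without a symbol, which was higher under isoflurane. At an unadjusted p under 0.05 there were 3210, where chance gives 1480, and the groups did not overlap for 15.1% of features, where chance gives 10%. Interferon response genes had a median of 0.33 with 23 of 27 members higher (camera adjusted p = 0.0155; adjusted p = 0.989 with an estimated correlation), and their mean signal was 1.33 in TBA isoflurane rat 2 against 0.30 and 0.49 in rats 1 and 3. The interferon median was 0.04 without TBA isoflurane array 2 (adjusted p = 0.919) and 0.17 without TBA CO2-O2 array 1 (adjusted p = 0.516). Genes of cholesterol synthesis had a median of 0.09 with 18 of 21 members higher (camera adjusted p = 0.0155; adjusted p = 0.989 with an estimated correlation). Fos (0.33 ± 0.19, adjusted p = 0.571), Per1 (0.24 ± 0.53, adjusted p = 0.908) and Vegfa (-0.03 ± 0.08, adjusted p = 0.914) did not pass. With scan day as a fixed term the count was 7, which is the fit without TBA CO2-O2 array 3. From the arrays of scan day 2 alone the count was 2. It was 1 without vehicle CO2-O2 array 1 or without any 1 of the vehicle isoflurane arrays, 0, 0 and 7 without TBA CO2-O2 array 1, 2 or 3, and 0 without any 1 of the TBA isoflurane arrays.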

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

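The tests of slide and of time of day for the anesthetics, the slide test for TBA, the scan day test for the proximal tubule lists and the tests of tubule share under each anesthetic were chosen after their results were seen.

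In 4 lists the TBA effect differed between the anesthetics by camera's test of the difference. The median difference, isoflurane minus CO2-O2, was 0.48 for proximal tubule S3 markers (adjusted p = 0.0183; adjusted p = 0.682 with an estimated correlation), 0.29 for cytokines and NF-kB targets (adjusted p = 0.0183; adjusted p = 0.682 with an estimated correlation), -0.24 for intercalated cell markers (adjusted p = 0.0183; adjusted p = 0.682 with an estimated correlation) and 0.44 for interferon response genes (adjusted p = 0.0299; adjusted p = 0.747 with an estimated correlation). The interferon difference was 0.09 without TBA isoflurane array 2 (adjusted p = 0.417) and 0.28 without TBA CO2-O2 array 1 (adjusted p = 0.243). With scan day as a fixed term, where the CO2-O2 effect rests on 1 TBA array, the interferon difference was 0.05. That of intercalated cells was -0.15 without TBA isoflurane array 1 (adjusted p = 0.159) or vehicle CO2-O2 array 1 (adjusted p = 0.0596). No member of these lists was called by limma over all genes, and 1 cytokine or NF-kB gene passed when adjusted over the list alone.

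The clock genes differed between the anesthetics. The clock difference, the mean of Bmal1, Npas2, Clock and Nfil3 minus that of 9 repressor and output genes, was -2.08 ± 0.28 (SE) for isoflurane minus CO2-O2 in vehicle rats and -1.91 ± 0.46 in TBA rats. Within scan day 2 it was -2.26 in TBA rats, which argues against scan day, but the arrays of that test lie on different slides, which its design had overlooked. With slide as a fixed term it was -3.13 ± 0.56 in vehicle rats, a value that rests on 1 TBA array of slide 1, so slide stays open. Time of day of the kill may also account for it: the Bmal1 arm was at -1.11 and the Per arm at 0.97 in vehicle rats, and without kill times in the labels the hour and the anesthetic cannot be told apart.

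The clock genes also differed between TBA and vehicle rats, in the opposite direction. The clock difference was 1.34 ± 0.27 averaged over the anesthetics and 1.42 ± 0.19 under isoflurane, within scan day 2. That argues against scan day, but these groups lie on different slides, and within slide 1 the difference was 0.55 ± 0.53 from 1 TBA array, so slide stays open. Across the 16 genes of the clock list the averaged TBA and anesthetic effects correlated at -0.968. A shift in the hour of the kill and an effect of TBA on the clock could each give that, so it does not decide between them. If TBA rats were killed at another hour, other rhythmic genes could move along the same axis. Across 29566 features outside the clock list the TBA and anesthetic effects correlated at -0.0190, against -0.306 to 0.245 in 100 regroupings. That spread is too wide to decide, and most of those genes need not be rhythmic. A shared shift in the hour of the kill and an effect of TBA on the clock both stay open as hypotheses.

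Proximal tubule S1-S2 and PPAR-alpha genes were higher as lists in the averaged effect (adjusted p = 0.673 and adjusted p = 0.535 with an estimated correlation), and with quantile normalization the S1-S2 median was 0.06 there and 0.01 under isoflurane. A larger share of proximal tubule taken from all other resident cell types alike would lower the markers of each of them. Under CO2-O2 3 of 9 such lists (distal convoluted tubule, intercalated cell, endothelium) lay above 0 by over 2 SE of their members and between rats. That argues against such a share as the whole cause there. Another 3 lay below 0 by over 2 SE of their members, among them thick ascending limb (-0.20 ± 0.08, SE between rats) and fibroblast (-0.26 ± 0.08). A shift in the mix of several cell types at once was not tested and stays open. Under isoflurane 7 of 9 and in the averaged effect 4 of 9 lay below 0, with 0 above by over 2 SE, so a larger share of proximal tubule in the TBA samples stays open under isoflurane. All isoflurane arrays were scanned on day 2, so values within scan day 2 are the isoflurane part of the averaged effect. The mean of the PPAR-alpha list there was 0.56 ± 0.22 (SE between rats), and 0.35 without vehicle array 3. That argues against scan day as the whole cause for this list under isoflurane. The mean of the S1-S2 list there was 0.15 ± 0.05 (SE between rats), but it depends on the scaling, as given above. Slide stays open for both lists because slide 3 held TBA rats alone. Time of day of the kill and an effect of TBA on these genes stay open as hypotheses: across the 42 members the TBA and anesthetic effects correlated at -0.332, but regroupings gave -0.958 to 0.938.

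Other splits of the same arrays were counted for each comparison. For the averaged effect 1 of 100 splits, the real one, called as many as 558, and the highest other called 4, a share under 0.05. Splits that mix TBA and vehicle rats put any treatment difference into the spread, which lowers their counts. The real split also partly follows the slides, so a low share does not tell TBA from slide. The 10 splits of 3 arrays against 3 are too few for a share under 0.05: under CO2-O2 the real split called 44 and the highest other 1, under isoflurane 117 and 1, between the anesthetics in vehicle rats 31 and 1, and in TBA rats 2 and 2 (as many in 2 of the splits). For the difference between the TBA effects the real count is 0, which all 100 splits reach by construction, so they say nothing about chance there. The highest other called 558, and that split swaps the treatment labels within isoflurane, which turns the difference into the averaged TBA effect and so shows that structure of the samples.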

How the results depend on the processing

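Scan day as a fixed term, slide 1 alone, scan day 2 alone and features with a symbol alone were chosen after seeing the data. Counts follow the order TBA under CO2-O2, TBA under isoflurane, averaged effect, difference of effects, anesthetic in vehicle rats and in TBA rats, which were 44, 117, 558, 0, 31 and 2. Where a count moved by over 1.5 times the cause was not tested unless given. With slide or scan day as a fixed term, and with slide 1 alone, the CO2-O2 effect rests on 1 TBA array. Counts from those fits for TBA under CO2-O2, the averaged effect and the difference therefore do not show whether calls hold. Normexp gave 67, 1337, 993, 7, 850 and 6 and a correlation of the TBA effects of 0.121. Without the filter on dim probes, which raises the features tested to 45877, there were 9, 3, 63, 0, 0 and 3 and the correlation was 0.107; with only probes above background on all 12 arrays 60, 145, 777, 2, 71 and 1. Quantile normalization gave 51 under isoflurane, 92 in vehicle and 5 in TBA rats; median scaling 308, 52 and 5. The share of higher calls was 83.1% with median scaling under isoflurane against 63.2%, 32.7% in vehicle rats against 54.8%, and 80.0% with either scaling of 5 calls in TBA rats against 1 of 2. The mean of a gene's probes gave 19, 51 and 18 (TBA under each anesthetic, vehicle rats). A trend with robust spread gave 108, 610, 1091, 2, 283 and 14, and array weights, which change with the order of the features, 102, 1033 and 654 (CO2-O2, averaged, vehicle rats). Only the arrays compared, with fewer degrees of freedom, gave 16, 0, 1 and 0, and a fold of at least 2, a stricter rule, 9, 22, 31 and 11. Slide as a random block gave 0, 324 and 3 (isoflurane, averaged, vehicle rats) and slide as a fixed term 75 under CO2-O2; it could be fitted for 2 comparisons alone, so list tests have no total with it. Scan day as a fixed term gave 136, 43 and 7 (averaged, difference, TBA rats), slide 1 alone 1, scan day 2 alone 0 under isoflurane, and features with a symbol 285 and 1 (averaged, TBA rats).

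Leaving out 1 array in turn gave 1 to 162, 0 to 98, 73 to 992, 0 to 5, 0 to 91 and 0 to 7; list calls ranged from 32 to 50 and the correlation from 0.0639 to 0.250. The replicate block gave 3, 0, 167, 0, 0 and 3; the numbers do not pair the rats, as 3 of 18 same-number pairs correlated over 0.1 (-0.133 to 0.133) and 5 of 12 arrays correlated best with their own number.

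Of 40 list calls, 0 held with an estimated correlation, 6 with fry, which called 7, and 24 with median scaling, which called 25. The median of the oxidative phosphorylation list turned to -0.0391 under isoflurane and -0.0145 in the averaged effect with quantile normalization. Over the alternatives, named genes kept direction and side of the threshold in 6850 cases, lost the threshold in 979, gained it in 102 and, with no call in either fit, changed direction in 56, such as Lcn2 and Havcr1; lists did so in 706 and lost it in 249. In the averaged effect Cldn22, Acaa1b and Slc5a12 passed in 25 of 25 alternatives and Bmal1 in 24, and under CO2-O2 Acot12 passed in 26 of 27. Others held less often: under CO2-O2 Slc5a12 in 9 of 27, Gckr in 8 and Pck1 in 6, under isoflurane Bmal1 in 11 of 27, Cldn22 in 9 and Rd3l in 4 of 26, and in the averaged effect Tef in 11 of 25 and Ptprq in 10. Signal over background limits the dim genes.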

Other observations

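Several responses known from solvents and drugs were measured in these kidneys and did not pass as lists in the averaged TBA effect. Markers of kidney injury had a median of 0.08 over 25 genes (camera adjusted p = 0.373), cell cycle genes 0.17 over 26 (adjusted p = 0.347), p53 targets 0.07 over 16 (adjusted p = 0.697), NRF2 targets 0.03 over 25 (adjusted p = 0.913), CAR and PXR targets 0.07 over 14 (adjusted p = 0.869) and lysosomal genes 0.03 over 30 (adjusted p = 0.510). Among CAR and PXR targets the efflux pump Abcc2 rose by 0.49 ± 0.10 (adjusted p = 0.0486), and among hypoxia targets Ndrg1 rose by 0.89 ± 0.11 (adjusted p = 0.00964). A p that misses the threshold does not show that these genes were alike in TBA and vehicle rats.

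The alpha-2u-globulin members varied more between rats of a group than most lists. Their mean signal was -4.35 and -4.49 in TBA CO2-O2 rats 1 and 2 and -1.33 in rat 3, and -0.65, -3.88 and -2.16 in TBA isoflurane rats 1, 2 and 3, against -1.02 to -0.48 in vehicle rats under CO2-O2 and -1.44 to 1.05 in vehicle rats under isoflurane.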
